A study of Homo sapiens with 9 samples.

How the data were processed

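Polyadenylated RNA of OCI-Ly1 cells was sequenced in 9 libraries, 3 for each of a scrambled control shRNA (shSCR) and 2 shRNAs against KDM1A. The labels describe shRNAs in the pLKO1 vector, puromycin selection and biological triplicates. The count table names the LSD1 shRNA libraries sh68 and sh72, after the last digits of their clone names, and the sample titles number them instead; no label says which number goes with which name, so the table's names are used throughout.

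The deposited table holds counts, whole numbers of reads per gene symbol and library, with no normalization. The submitters' processing notes name CASAVA 1.8.2, STAR 2.5.2, featureCounts 1.5.2 and the hg38 genome. Their parameters, the gene annotation and the strand setting are not given in the sources used here. The table has 26816 genes and none with 0 reads in every library, and all 9 columns were used. Since the strand setting is unknown, reads where exons of 2 genes overlap cannot be assigned with certainty, and overlaps are named beside the genes concerned. Positions come from RefSeq on GRCh38.p14, which held 23569 of the symbols, and GC content and transcript length from GENCODE 29, which held 19370. Placeholder names beginning with LOC were treated as having no symbol.

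Counts were fitted with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr with the groups and its default minimums, which left 15725, and libraries were scaled by TMM. One quasi-likelihood model with a term per group was fitted to all 9 libraries, with a common biological coefficient of variation of 0.0394. The contrasts were the mean of both LSD1 shRNAs against shSCR, each shRNA against shSCR, and sh72 minus sh68. P values were adjusted over all genes tested by the method of Benjamini and Hochberg, and genes with an adjusted p below 0.05 are called changed. The SE beside a log2 fold change is its absolute value over the square root of the F statistic. For genes moved the same way by each shRNA, the count was set against the product of the separate counts and against 20 simulated pairs of unchanged groups that share the control libraries.

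Gene lists, 35 in number, were written from general knowledge. They cover the LSD1 and CoREST complex, BCL6-repressed genes, corepressors of BCL6, germinal-centre B cells, plasma cells, memory B cells and activation, NF-kB and CD40 targets, B-cell receptor signalling, MHC class I and class II, interferon-stimulated genes, RNA interference and double-stranded RNA factors, migration and adhesion, G1/S and replication, and G2/M and mitosis. Further lists hold p53 targets, the BCL2 family, nucleolar MYC targets, cytosolic ribosomal proteins, mitochondrially encoded genes, oxidative phosphorylation, glycolysis and hypoxia, cholesterol synthesis, ATF4 and the unfolded protein response, heat shock, neuronal targets of REST and CoREST, LSD1-responsive myeloid genes, histones, housekeeping genes, and markers of T cells, natural killer cells, monocytes and macrophages, erythroid cells, fibroblasts and stroma, and epithelium. Lists with at least 5 tested members, 32 of them, were tested with camera on log2 CPM with a preset correlation of 0.01, adjusted over the lists of a contrast. Beside it stand camera with an estimated correlation, which ended every list call, and fry, which tests a list's own genes and compares them with no others. Members were counted over all genes tested and again adjusted over the list alone.

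The genes named were taken by a rule. For the mean of both shRNAs these were the 12 highest and 12 lowest log2 fold changes among genes that passed there and in each single contrast with the same sign, with all 6 LSD1 shRNA libraries beyond all 3 controls, an average log2 CPM of at least 1 and a symbol. For each other contrast the 5 highest and 5 lowest were taken by the same kind of rule, and for each list up to 4 passing members with the largest change on the mean. Among those fixed by name were BCL6, PRDM1, IRF4, CD80, CD69, CDKN1A, MYC, RCOR1, HDAC1, HDAC2, GFI1 and KDM1B. A few genes that the rule or the fixed names took are not reported here. Genes outside the rule are said to be chosen after their values were seen. The groups, contrasts, lists, naming rule and alternatives, other than those said to be added later, were fixed before the data were examined.

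Alternatives were RLE scaling, library size alone, no filter, a minimum of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, only the groups compared, the replicate number as a block, a robust fit, a minimum of 1.5-fold, and each library left out in turn. Leaving genes over 1% of counts out of the library size moved nothing, since 0 genes exceed it. Offsets for GC content and transcript length, and leaving out genes of the MHC region and pseudoautosomal region 1, were added after seeing the data. The replicate numbers gave little sign of pairing libraries across groups. The residuals of libraries with the same number had Pearson r from -0.036 to 0.072 across genes, and those with different numbers from -0.082 to 0.056. Of the 9 libraries, 6 correlated best with a library of their own number in another group, so weak pairing cannot be excluded.

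The pipeline was tested on simulated data in which 50 genes each were changed by 1.25, 1.5, 2 and 3-fold in both LSD1 shRNA groups. It recovered 32, 48, 48 and 50 of them, with 14 false calls of 192. The changed genes were drawn from those with a mean above 1 CPM, so recovery in genes with fewer reads was not measured. Far fewer genes were changed than passed in the data. Library totals ran from 29506767 to 35270849 reads. The reads carry no molecular identifiers, so the floor of 3 reads set for genes at 0, and the intervals at 95%, cover counting error only. Single values of KDM1A, as log2 CPM, were compared by exact permutation in R. Counts and annotation were read, and shares of absent genes compared, in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Figures were drawn with matplotlib 3.10.9. Immunoglobulin and T-cell receptor genes were not named.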

Results

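RNA was sequenced from OCI-Ly1 cells, a human line of diffuse large B-cell lymphoma of the germinal-centre type, in 9 libraries. The groups were cells with a scrambled control shRNA (shSCR), and cells with either of 2 shRNAs against KDM1A, named here sh68 and sh72 as in the count table, with 3 biological replicates each. KDM1A encodes LSD1, a histone demethylase that removes methyl groups from lysine 4 of histone H3 and works in complexes with CoREST. The libraries held 32835510, 29506767 and 31726959 counted reads in shSCR, 32230566, 35270849 and 35067557 in sh68, and 34592653, 30994661 and 29857865 in sh72. Mitochondrially encoded genes took 5.23 ± 0.0905% of counts in shSCR, 5.37 ± 0.138% in sh68 and 4.69 ± 0.125% in sh72, and cytosolic ribosomal protein genes 3.39 ± 0.0931%, 3.56 ± 0.132% and 3.17 ± 0.112%. Of 26816 genes in the table, 15725 were tested. Across genes, the lowest Pearson correlation between libraries of a group was 0.995. The first 2 principal components held 44.6% and 33.9% of the variance. On the first, sh68 scored 40.56 to 45.5, apart from shSCR (-29.28 to -27.45) and sh72 (-18.62 to -12.54). On the second, sh68 (5.81 to 7.99) lay between shSCR (28.81 to 29.99) and sh72 (-37.98 to -34.26). Values after a gene name are log2 fold changes ± SE from the edgeR fit unless a unit is given, and CPM are means ± SD over 3 libraries.

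KDM1A RNA fell with both shRNAs. The gene lies on chromosome 1 (GRCh38.p14, 23019468 to 23083689). Its reads numbered 3915, 3463 and 3850 in the shSCR libraries, 761, 847 and 910 in sh68, and 654, 719 and 638 in sh72. These are 121 ± 1.44, 24.4 ± 1.26 and 20.9 ± 1.82 CPM, so that 20.2% of the control level was left with sh68 and 17.2% with sh72. The log2 fold change was -2.31 ± 0.054 with sh68 (adjusted p = 2.76e-20) and -2.54 ± 0.056 with sh72 (adjusted p = 5.15e-20). Every LSD1 shRNA library lay below every control library, with a two-sided exact permutation p of 0.0119 for 6 libraries against 3 and of 0.1 for each shRNA alone, each the smallest that its design allows. The difference of sh72 minus sh68 was -0.23 ± 0.061 (adjusted p = 0.00261). KDM1B, the paralog of KDM1A, had -0.03 ± 0.038 on the mean of both shRNAs and did not pass the test (adjusted p = 0.538).

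**Figure D1:**
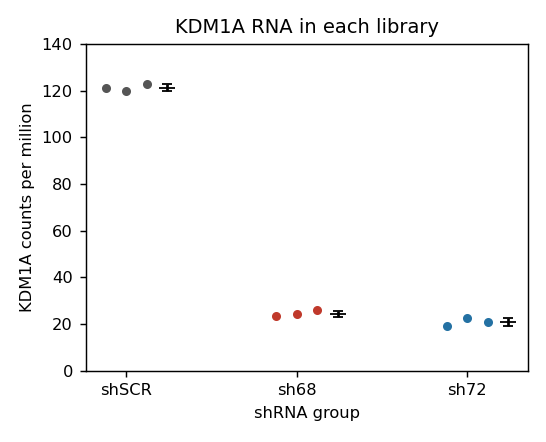
KDM1A level in CPM in each of the 9 libraries (vertical axis from 0) by shRNA group (horizontal axis), with each group's mean and SD beside its points. The 6 libraries with an LSD1 shRNA lie near 24.4 and 20.9, below the 3 control libraries near 121.

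The mean of both shRNAs against shSCR asks what the cells' RNA does when LSD1 is depleted. Apart from KDM1A and LRRC32, the 12 largest falls by the naming rule were in genes induced by interferon. IFI44L fell by 3.36 on the log2 scale, IFIT1 by 2.65 and USP18 by 2.33, and IFI44 fell from 250.5 ± 7.79 CPM to 16.4 ± 2.57 with sh68 and 120.2 ± 7.88 with sh72. LRRC32, which encodes GARP, a surface protein that binds latent TGF-beta, fell from 31.5 ± 4.93 CPM to 4.48 ± 0.146 with sh68 and 3.52 ± 0.519 with sh72. The largest rises were in genes barely read in control cells: PCDH9, a protocadherin, rose 12.1-fold from 0.408 ± 0.0774 CPM, and ERBB4, a receptor tyrosine kinase, rose 11.5-fold from 0.624 ± 0.273 CPM. Also among the 12 largest rises were DTHD1 3.18 ± 0.20, MYBPC1 3.13 ± 0.17, TMEM71 2.89 ± 0.23, PDE4A 2.56 ± 0.18, SCIMP 2.46 ± 0.16, KLRC1 2.44 ± 0.14, PART1 2.40 ± 0.084, RNF125 2.39 ± 0.20 and LINC01054 2.35 ± 0.14. PDE4A encodes a cyclic AMP phosphodiesterase, SCIMP an adaptor of antigen-presenting cells, and KLRC1 the natural killer cell receptor NKG2A. The other large falls were XAF1 -2.31 ± 0.048, DDX60 -2.25 ± 0.059, IFIT3 -2.25 ± 0.092, RSAD2 -2.11 ± 0.085, ISG15 -2.08 ± 0.077 and IFITM1 -2.02 ± 0.076. Exons of KLRC1 overlap those of KLRC2, those of PART1 overlap PDE4D, those of RSAD2 overlap CMPK2, and those of IFITM1 overlap IFITM2, so some of these reads may belong to the neighbour.

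In all, 8226 genes passed, 3908 higher and 4318 lower (4475 and 3689 with library size alone as the scaling), of which 744 and 222 changed at least 2-fold and 151 and 26 at least 4-fold. The rule for naming genes was met by 3074 genes, 1328 higher and 1746 lower. In a fit of the 6 LSD1 shRNA libraries as 1 group, where the difference between the shRNAs adds to the spread, 3581 genes passed, and IFI44L, IFIT1, IFI44, DDX60 and RSAD2 were not among them. With a minimum of 1.5-fold, 1470 rose and 689 fell. Of 150 named genes that passed on the mean, 109 passed the same way with each shRNA, and the others are listed by shRNA further on.

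Genes induced by interferon fell almost as a block. Of 40 measured members of the list, 39 fell and 0 rose (39 and 0 adjusted over the list alone). The median was -1.11 (camera adjusted p = 5.83e-21, and adjusted p = 0.913 with an estimated correlation). ISG15, a ubiquitin-like modifier, fell from 299 ± 44.4 CPM to 38.7 ± 1.32 with sh68 and 129.8 ± 25.2 with sh72. USP18 removes ISG15 from proteins. Of factors for RNA interference and double-stranded RNA, 1 of 16 measured members rose, 8 fell and 7 did not pass (1 and 8 adjusted over the list alone). The median was -0.089 and the list did not pass (camera adjusted p = 0.151). EIF2AK2, the RNA-dependent kinase PKR, which is also in the interferon list, fell (-0.68 ± 0.037), as did the RNA editing enzyme ADAR (-0.67 ± 0.032) and DICER1 (-0.40 ± 0.039), while TNRC6A rose (0.21 ± 0.034). In the MHC class I list, 2 of 13 measured members rose, 6 fell and 5 did not pass (2 and 6 adjusted over the list alone). The median was -0.12 (camera adjusted p = 0.368). Its proteasome activators PSME1 (-0.51 ± 0.035) and PSME2 (-0.36 ± 0.039) and the immunoproteasome subunit PSMB10 (-0.34 ± 0.062) fell. For MHC class II, 3 of 9 measured members rose, 5 fell and 1 did not pass (3 and 5 adjusted over the list alone). The median was -0.11 (camera adjusted p = 0.884). HLA-DOB (-1.29 ± 0.24) and the invariant chain CD74 (-0.16 ± 0.034) fell and the regulator RFXAP rose (0.39 ± 0.071). Both MHC lists were measured in part, since many genes of the region on chromosome 6 are absent from the table or hold few reads.

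Genes that mark B-cell states changed in both directions, as did genes as a whole. Of the 15725 genes tested, 52.3% passed on the mean, 3908 higher and 4318 lower, and the counts of list members are to be read beside that share. Among genes repressed by BCL6, the transcription factor that holds B cells in the germinal centre, 12 of 31 measured members rose, 11 fell and 8 did not pass (12 and 11 adjusted over the list alone). CD69, an early activation marker that keeps lymphocytes in tissue, rose (2.12 ± 0.22), while PTPN6, the phosphatase SHP-1, fell (-1.73 ± 0.043). The list's median was 0.037, its mean -0.017 and its test pointed up (camera adjusted p = 0.943). BCL6 itself fell slightly (-0.15 ± 0.032), and PRDM1, the regulator of plasma cell fate, had 0.33 ± 0.33 and did not pass. In the list of memory B cells and activation, 8 of 24 measured members rose, 10 fell and 6 did not pass (8 and 10 adjusted over the list alone). Beside CD69, rises of this list were in the costimulatory ligand CD80 (1.39 ± 0.11) and in SAMSN1 (1.22 ± 0.092), an adaptor that dampens B-cell activation. Its median was -0.048, its mean 0.14 and its test pointed up (camera adjusted p = 0.976). For germinal-centre B cells, 10 of 32 measured members rose, 11 fell and 11 did not pass (10 and 11 adjusted over the list alone). The median was 0.021, its mean -0.006 and its test pointed up (camera adjusted p = 0.943). This averaged opposite moves. With sh68 19 rose and 8 fell (median 0.19, camera adjusted p = 0.0268), and with sh72 9 rose and 16 fell (median -0.19, camera adjusted p = 0.282). LMO2 (-1.69 ± 0.19), VPREB3 (-1.16 ± 0.045) and SERPINA9 (-1.06 ± 0.10), markers of the germinal centre in lymphoma, fell. In the plasma cell list, 10 of 21 measured members rose, 5 fell and 6 did not pass (10 and 5 adjusted over the list alone). The median was 0.16 (camera adjusted p = 0.326). XBP1, the transcription factor of the secretory programme, rose (0.79 ± 0.045). TNFRSF17, the receptor BCMA, passed on the mean (0.79 ± 0.065) and with sh68 but not with sh72, with a difference of sh72 minus sh68 of -1.32.

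Members of B-cell receptor signalling fell more often than they rose. There, 5 of 30 measured members rose, 15 fell and 10 did not pass (8 and 16 adjusted over the list alone). The median was -0.11 (camera adjusted p = 0.0241, and adjusted p = 0.913 with an estimated correlation). PTPN6, a brake on the receptor, and PRKCB (-1.35 ± 0.052), a kinase on the path to NF-kB, had the largest falls, and CD79A, a chain of the receptor, fell as well (-0.64 ± 0.043, passing with sh72 but not with sh68). This call was lost with offsets for GC content and transcript length, where the median was -0.053 and the adjusted p 0.0945, the largest over 16 alternatives. Of the NF-kB and CD40 targets, 6 of 22 measured members rose, 9 fell and 7 did not pass (6 and 9 adjusted over the list alone). The median was -0.13 (camera adjusted p = 0.589). STAT5A, a transducer of cytokine signals, rose (1.73 ± 0.11), and the surface proteins CD83 (-0.75 ± 0.041) and CD40 (-0.66 ± 0.041) and the NF-kB inhibitor NFKBID (-0.55 ± 0.066) fell. For migration and adhesion, 11 of 24 measured members rose, 10 fell and 3 did not pass (11 and 10 adjusted over the list alone). The median was 0.041 (camera adjusted p = 0.517). GPR183 (0.78 ± 0.039), a receptor that guides lymphocytes within tissue, rose. The receptors S1PR4 (1.12 ± 0.20) and CXCR4 (0.70 ± 0.043) passed on the mean but not with sh72 alone (0.55 ± 0.24 and -0.069 ± 0.049), nor in the fit of the 6 LSD1 shRNA libraries as 1 group. Of the BCL2 family of cell death regulators, 6 of 15 measured members rose, 4 fell and 5 did not pass (6 and 4 adjusted over the list alone). The median was 0.006 (camera adjusted p = 0.834). The death-promoting members PMAIP1 (0.68 ± 0.036), BBC3 (0.40 ± 0.074) and BAD (0.27 ± 0.061) rose and the protective member MCL1 fell (-0.31 ± 0.031). BBC3 and BAD passed with sh68 but not with sh72. Among p53 targets, 7 of 27 measured members rose, 12 fell and 8 did not pass (7 and 12 adjusted over the list alone). The median was -0.044, its mean 0.004 and its test pointed down (camera adjusted p = 0.884). MDM2 (0.89 ± 0.041), the ligase that degrades p53, and TP53INP1 (0.83 ± 0.042) rose, PLK3 (-0.57 ± 0.13) and the death receptor TNFRSF10B (-0.56 ± 0.042) fell, and CDKN1A, the cell cycle inhibitor p21, had 0.037 ± 0.038 and did not pass. Exons of CD80 overlap those of TIMMDC1, those of MDM2 overlap CPM and those of TNFRSF10B overlap RHOBTB2.

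Lists of metabolism and stress had medians from -0.23 to 0.19. Cholesterol synthesis fell: 5 of 24 measured members rose, 17 fell and 2 did not pass (5 and 17 adjusted over the list alone). The median was -0.16 (camera adjusted p = 0.0241, and adjusted p = 0.913 with an estimated correlation). MSMO1 (-0.98 ± 0.037), TM7SF2 (-0.71 ± 0.04), LSS (-0.49 ± 0.058) and MVD (-0.43 ± 0.044), enzymes of the pathway, were its largest falls. Of genes of glycolysis and hypoxia, 7 of 30 measured members rose, 17 fell and 6 did not pass (7 and 18 adjusted over the list alone). The median was -0.23 (camera adjusted p = 0.0489, and adjusted p = 0.913 with an estimated correlation). The mTORC1 inhibitor DDIT4 (-1.25 ± 0.067) and the angiogenic factor VEGFA (-1.03 ± 0.071) fell, and the glucose transporter SLC2A3, at 0.185 ± 0.0493 CPM in shSCR, rose (1.29 ± 0.37). The list of ATF4 targets and the unfolded protein response rose: 20 of 30 measured members rose, 4 fell and 6 did not pass (21 and 4 adjusted over the list alone). The median was 0.19 (camera adjusted p = 0.0241, and adjusted p = 0.913 with an estimated correlation). Its largest rise was XBP1, and SEL1L, a part of the machinery that degrades misfolded proteins, fell (-0.66 ± 0.035). VLDLR rose (0.44 ± 0.089). For heat shock, 5 of 12 measured members rose, 4 fell and 3 did not pass (5 and 4 adjusted over the list alone). The median was 0.012 (camera adjusted p = 0.771). The chaperones HSPB1 (0.74 ± 0.068) and DNAJB1 (0.35 ± 0.04) and the cochaperone BAG3 (0.64 ± 0.13) rose and DNAJA1 fell (-0.30 ± 0.032). In oxidative phosphorylation, 4 of 32 measured members rose, 8 fell and 20 did not pass (4 and 8 adjusted over the list alone). The median was -0.027 (camera adjusted p = 0.717). This averaged opposite moves. With sh68 1 rose and 15 fell (median -0.097, camera adjusted p = 0.0355), and with sh72 11 rose and 3 fell (median 0.056, camera adjusted p = 0.34). On the mean its largest changes were CYC1 -0.31 ± 0.036, SDHD -0.27 ± 0.04, NDUFB5 0.21 ± 0.037 and NDUFV1 -0.18 ± 0.038. Of the mitochondrially encoded genes, 4 of 13 measured members rose, 6 fell and 3 did not pass (4 and 6 adjusted over the list alone). The median was -0.076 (camera adjusted p = 0.771). ND1 (0.41 ± 0.038) and ND5 (0.20 ± 0.034) rose and COX1 (-0.28 ± 0.031) and COX2 (-0.25 ± 0.037) fell.

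On the mean of both shRNAs the G1/S list rose and the G2/M list fell, and with sh72 alone neither passed, with medians of 0.07 (adjusted p = 0.441) and -0.049 (adjusted p = 0.34). In the G1/S and replication list, 20 of 35 measured members rose, 4 fell and 11 did not pass (20 and 4 adjusted over the list alone). The median was 0.13 (camera adjusted p = 0.033, and adjusted p = 0.959 with an estimated correlation). GINS2 (0.40 ± 0.037) and CDC6 (0.35 ± 0.035), which load and start the replicative helicase, and the polymerase subunit POLE2 (0.34 ± 0.048) rose, and the transcriptional repressor E2F8 fell (-0.31 ± 0.038). In the G2/M list, 2 of 36 measured members rose, 20 fell and 14 did not pass (2 and 20 adjusted over the list alone). The median was -0.11 (camera adjusted p = 0.0307, and adjusted p = 0.973 with an estimated correlation). ANLN (-0.58 ± 0.037), which builds the contractile ring, the kinase NEK2 (-0.55 ± 0.054) and the kinesins KIF2C (-0.37 ± 0.04) and KIF23 (-0.32 ± 0.042) fell. In the list of MYC targets of the nucleolus, 3 of 30 measured members rose, 15 fell and 12 did not pass (3 and 17 adjusted over the list alone). The median was -0.088 (camera adjusted p = 0.033, and adjusted p = 0.973 with an estimated correlation). With sh72 alone the MYC list had a median of 0.02 (adjusted p = 0.704), with 8 members higher and 6 lower, so that the fall was seen with sh68. On the mean its largest falls were in the ribosome assembly genes MYBBP1A -0.38 ± 0.041, RRP9 -0.37 ± 0.052 and NOB1 -0.27 ± 0.04 and in ODC1 (-0.29 ± 0.041), an enzyme of polyamine synthesis. Among cytosolic ribosomal proteins, 4 of 46 measured members rose, 15 fell and 27 did not pass (4 and 12 adjusted over the list alone). The median was -0.05 (camera adjusted p = 0.368). RPS3 (-0.51 ± 0.035) and RPL38 (-0.39 ± 0.038) fell and RPLP1 rose (0.39 ± 0.04). Of the histone genes, 3 of 15 measured members rose, 1 fell and 11 did not pass (2 and 0 adjusted over the list alone). The median was 0.045 (camera adjusted p = 0.771). HIST1H2BK (0.73 ± 0.093) and H2AFX (0.73 ± 0.08) rose. In the housekeeping list, 7 of 20 measured members rose, 7 fell and 6 did not pass (7 and 7 adjusted over the list alone). The median was 0.048, its mean -0.017 and its test pointed down (camera adjusted p = 0.976). CHMP2A (-0.47 ± 0.037), PGK1 (-0.39 ± 0.041) and YWHAZ (-0.31 ± 0.034) fell and HPRT1 rose (0.39 ± 0.033).

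Partners of LSD1 changed in both directions, as did the 52.3% of all genes tested that passed on the mean (3908 higher and 4318 lower). In the list of the LSD1 and CoREST complex, 7 of 24 measured members rose, 13 fell and 4 did not pass (7 and 13 adjusted over the list alone). The median was -0.13 (camera adjusted p = 0.368). The transcriptional repressor GFI1B, at 1.45 ± 0.214 CPM in shSCR, fell (-1.15 ± 0.22), and its paralog GFI1 (0.44 ± 0.043), ZNF217 (0.48 ± 0.034), the scaffold RCOR1 (0.31 ± 0.039), and the deacetylases HDAC1 (0.10 ± 0.034) and HDAC2 (0.14 ± 0.03) rose. GFI1 and HDAC1 passed with sh68 but not with sh72. For corepressors of BCL6, 7 of 20 measured members rose, 8 fell and 5 did not pass (8 and 9 adjusted over the list alone). The median was -0.064 (camera adjusted p = 0.884). PCGF1 (-0.40 ± 0.07) and TBL1X (-0.29 ± 0.042) fell, and EZH2, which methylates lysine 27 of histone H3, rose (0.25 ± 0.034). KMT2D, a methyltransferase that the list holds although it is not a corepressor, fell (-0.27 ± 0.032). Of the neuronal targets of REST and CoREST, 4 of 18 measured members rose, 5 fell and 9 did not pass (4 and 5 adjusted over the list alone). The median was -0.082, its mean 0.016 and its test pointed down (camera adjusted p = 0.884). This averaged opposite moves. With sh68 7 rose and 3 fell (median 0.25, camera adjusted p = 0.225), and with sh72 2 rose and 10 fell (median -0.56, camera adjusted p = 0.0998). On the mean, the glutamate receptor subunit GRIN1 rose (2.20 ± 0.34), and the acetylcholine receptor subunit CHRNB2 (-1.11 ± 0.17) and the tubulin TUBB3 (-0.72 ± 0.075) fell. Of the myeloid genes that respond to LSD1 loss in other cells, 3 of 12 measured members rose, 4 fell and 5 did not pass (3 and 4 adjusted over the list alone). The median was -0.21, its mean 0.28 (-0.21 without LYZ) and its test pointed down (camera adjusted p = 0.986). LY96, the partner of TLR4, rose (0.93 ± 0.073). LYZ, lysozyme, had 0 reads in the control libraries, 81 in the sh68 libraries and 4 in the sh72 libraries. With sh68 it was at least 24.8-fold higher than the 0.0319 CPM that 3 reads over the control group would give.

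Genes of other cell types changed in both directions, again beside 52.3% of all genes tested that passed on the mean. For T cells, 3 of 10 measured members rose, 2 fell and 5 did not pass (3 and 2 adjusted over the list alone). The median was 0.087 (camera adjusted p = 0.717). IL7R, the receptor for interleukin 7, rose (2.11 ± 0.056), as did CD247 (0.50 ± 0.11), and CD5, also found on some B cells, fell (-1.82 ± 0.25). Of 3 measured natural killer cell genes, too few for a list test, 3 rose and 0 fell (3 and 0 adjusted over the list alone), namely KLRC1, KLRD1 (2.24 ± 0.28) and the pore-forming protein PRF1 (0.92 ± 0.089). In the monocyte and macrophage list, 2 of 5 measured members rose, 1 fell and 2 did not pass (2 and 2 adjusted over the list alone). The median was -0.19, its mean 1.46 (0.42 without LYZ, which had 0 control reads) and its test pointed up (camera adjusted p = 0.884). CLEC7A, a receptor for fungal glucans, rose from 0.0838 ± 0.0726 CPM (2.91 ± 0.51), and CD68 fell (-0.43 ± 0.11). For fibroblasts and stroma, 3 of 5 measured members rose, 0 fell and 2 did not pass (3 and 0 adjusted over the list alone). The median was 0.71 (camera adjusted p = 0.219). COL1A1 (2.07 ± 0.29), SPARC (1.74 ± 0.34) and FN1 (0.71 ± 0.13), genes of the extracellular matrix, rose. SPARC and FN1 passed with sh68 but not with sh72. Of 2 measured epithelial genes, 0 rose and 1 fell (0 and 1 adjusted over the list alone), EPCAM (-0.55 ± 0.068), and of 11 erythroid genes 0 were measured.

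Of 32 lists tested on the mean of both shRNAs, 8 passed camera. With an estimated correlation 0 passed (1 at an unadjusted p under 0.05), while fry, which asks whether a list's own genes move one way, called 22. Without sh68 replicate 1, or with a minimum of 1 CPM in 3 libraries, 5 lists passed. The interferon, cholesterol and ATF4 lists passed under each of 16 other settings, whereas the G1/S call was lost without shSCR replicate 3 or sh72 replicate 1 (adjusted p up to 0.0785), and the G2/M call with the minimum of 1 CPM and without sh68 replicate 1 or sh72 replicate 2 (up to 0.0733). Glycolysis was lost without shSCR replicate 2, sh68 replicate 1 or 3, or sh72 replicate 1 (up to 0.0833), with the minimum of 1 CPM (0.0568), with the replicate number as a block (0.0607) and with offsets for GC content and length (0.0945). The MYC list was lost with the minimum of 1 CPM and without shSCR replicate 1, sh68 replicate 1 or 3, or sh72 replicate 2 or 3 (up to 0.0836). Over all alternatives the medians ran from 0.10 to 0.16 for G1/S, -0.13 to -0.076 for G2/M, -0.24 to -0.18 for glycolysis and -0.13 to -0.055 for the MYC list. Of the 8, the interferon and cholesterol lists and those of G1/S, G2/M, MYC and glycolysis passed with sh68 alone, and the interferon, B-cell receptor and ATF4 lists with sh72 alone. With sh72, cholesterol synthesis had a median of -0.17 (adjusted p = 0.0932) and glycolysis -0.07 (adjusted p = 0.505). With sh68, B-cell receptor signalling had -0.032 (adjusted p = 0.693) and the ATF4 list 0.13 (adjusted p = 0.225).

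Of 150 named genes that passed on the mean, 109 passed the same way with each shRNA. With sh68 alone 25 did, namely MYL4, TMEM2, RAG1, VLDLR, BBC3, BAD, CCND2, RPS18, SLC2A3, H3F3A, GFI1, LYZ, S1PR4, CXCR4, NOB1, EPCAM, SPARC, FN1, CYC1, NDUFV1, PLK3, IRF4, TNFRSF17, MYC and HDAC1. With sh72 alone 15 did, namely ZDHHC8, CHAC1, CR2, CD79A, RPS3, E2F8, HIST2H2AC, CIITA, COX2, CD68, CD3D, CD247, NDUFB5, SLAMF7 and TNRC6A, and HLA-B passed with neither. The shRNAs moved TMEM2, RAG1, CIITA and NOB1 in opposite directions.

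For 13 named genes, the call on the mean was lost when 1 of certain libraries was left out. Each is given with its range over all alternatives and those libraries. They were ADM -0.84 ± 0.20 (-0.99 to -0.41, lost without shSCR replicate 1), CHAC1 0.44 ± 0.14 (0.34 to 0.59, lost without shSCR replicate 3), CCND2 1.93 ± 0.59 (1.505 to 2.56, lost without shSCR replicate 2), CD3D 2.09 ± 0.66 (1.655 to 2.29, lost without shSCR replicate 3 or sh68 replicate 3), CIITA -0.21 ± 0.056 (-0.26 to -0.12, lost without shSCR replicate 1), IRF4 1.05 ± 0.35 (0.88 to 1.26, lost without shSCR replicate 2 or 3), SLAMF7 1.27 ± 0.40 (0.80 to 2.58, lost without shSCR replicate 1 or 3) and CR2 1.13 ± 0.44 (0.92 to 1.40, lost without shSCR replicate 2 or 3 or sh68 replicate 2 or sh72 replicate 3). The same held for H3F3A 0.24 ± 0.094 (0.20 to 0.31, lost without shSCR replicate 1 or 2 or sh68 replicate 3 or sh72 replicate 3), HLA-B -0.74 ± 0.27 (-0.79 to -0.64, lost without shSCR replicate 1 or 2 or 3 or sh68 replicate 3 or sh72 replicate 3), MYC -0.11 ± 0.035 (-0.13 to -0.073, lost without shSCR replicate 1 or 2 or sh68 replicate 2 or 3 or sh72 replicate 2 or 3), HIST2H2AC -0.79 ± 0.33 (-1.01 to -0.40, lost without shSCR replicate 1 or 3 or sh68 replicate 1 or 2 or 3 or sh72 replicate 2) and RPS18 -0.51 ± 0.22 (-0.61 to -0.36, lost without shSCR replicate 1 or 2 or 3 or sh68 replicate 2 or 3 or sh72 replicate 1 or 3). IRF4 is a regulator of plasma cell fate, and CIITA the master regulator of MHC class II genes.

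**Figure D2:**
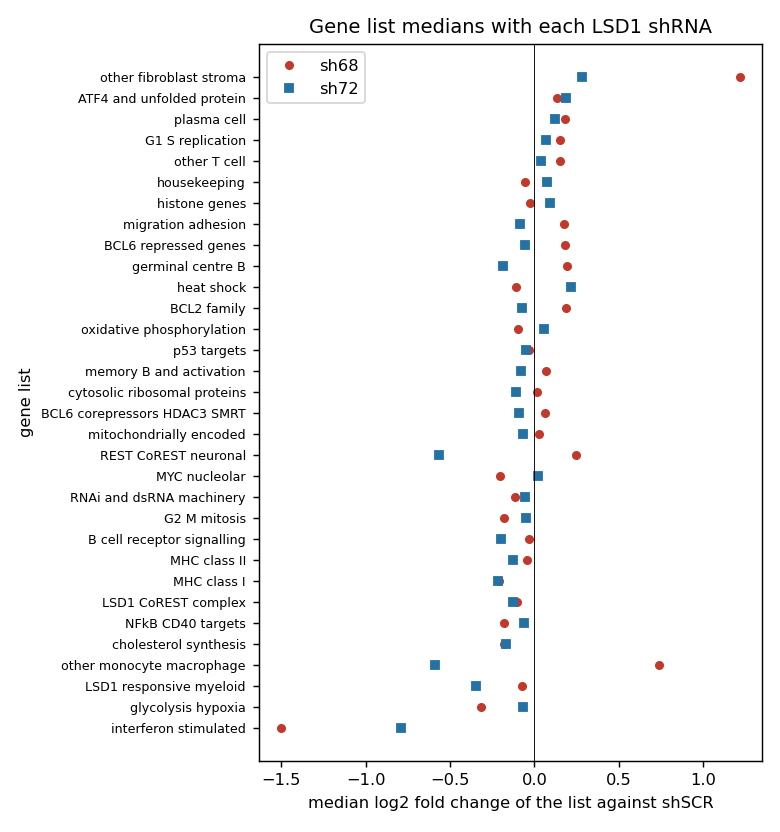
Median log2 fold change against shSCR (horizontal axis) of each of the 32 gene lists tested (vertical axis), with circles for sh68 and squares for sh72. The interferon-stimulated list lies lowest with both, at -1.50 with sh68 and -0.79 with sh72.

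With sh68 alone, IL7R rose 10.6-fold, from 9.92 ± 0.44 to 105 ± 5.24 CPM. PCDH9 (4.21 ± 0.17), ERBB4 (3.57 ± 0.19) and PRR5L (3.36 ± 0.16), a regulator of mTORC2, were the other large rises. IFI44L fell to 3.36 ± 0.916 CPM from 177 ± 11.5 (-5.71 ± 0.091), followed by IFIT1 (-4.26 ± 0.12), IFI44 (-3.93 ± 0.069), the helicase DDX60 (-3.59 ± 0.08) and OASL (-3.57 ± 0.15). In the interferon list, 40 of 40 members fell (40 adjusted over the list alone). The median was -1.50 (camera adjusted p = 5.1e-24, and adjusted p = 0.616 with an estimated correlation). Of the germinal-centre B-cell list, 19 of 32 measured members rose, 8 fell and 5 did not pass (20 and 8 adjusted over the list alone). The median was 0.19 (camera adjusted p = 0.0268, and adjusted p = 0.616 with an estimated correlation), a call lost without shSCR replicate 3 (adjusted p = 0.0519, the largest over 16 alternatives). In the G1/S list, 21 of 35 measured members rose, 2 fell and 12 did not pass (21 and 2 adjusted over the list alone). The median was 0.15 (camera adjusted p = 0.00682, and adjusted p = 0.616 with an estimated correlation). For G2/M, 3 of 36 measured members rose, 22 fell and 11 did not pass (3 and 22 adjusted over the list alone). The median was -0.18 (camera adjusted p = 0.00682, and adjusted p = 0.766 with an estimated correlation). In the MYC list of the nucleolus, 1 of 30 measured members rose, 25 fell and 4 did not pass (1 and 26 adjusted over the list alone). The median was -0.20 (camera adjusted p = 4.09e-05, and adjusted p = 0.616 with an estimated correlation). In glycolysis and hypoxia, 5 of 30 measured members rose, 19 fell and 6 did not pass (5 and 19 adjusted over the list alone). The median was -0.32 (camera adjusted p = 0.00682, and adjusted p = 0.616 with an estimated correlation). In cholesterol synthesis, 2 of 24 measured members rose, 15 fell and 7 did not pass (2 and 15 adjusted over the list alone). The median was -0.18 (camera adjusted p = 0.0153, and adjusted p = 0.616 with an estimated correlation).

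Oxidative phosphorylation fell with sh68, where 1 of 32 measured members rose, 15 fell and 16 did not pass (1 and 15 adjusted over the list alone). The median was -0.097 (camera adjusted p = 0.0355, and adjusted p = 0.766 with an estimated correlation). Among its members CYC1, a subunit of complex III, had -0.60 ± 0.043 and NDUFV1, a subunit of complex I, -0.41 ± 0.044. This call was lost with library size alone as the scaling, with the minimum of 1 CPM, and without shSCR replicate 1 or sh68 replicate 1 or 3, with an adjusted p up to 0.118. Its median ran from -0.12 to -0.063, the value closest to 0 without sh68 replicate 1. In all, 8727 genes passed with sh68, 4309 higher and 4418 lower (4655 and 3947 with library size alone), of which 1174 and 276 changed at least 2-fold, and with a minimum of 1.5-fold 2054 rose and 801 fell. By camera 8 lists passed, and 0 with an estimated correlation (1 at an unadjusted p under 0.05, and 24 by fry).

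With sh72 alone, ERBB4 (3.48 ± 0.19), DTHD1 (3.17 ± 0.22), MYBPC1 (3.14 ± 0.19), PCDH9 (2.98 ± 0.20) and AGR2 (2.77 ± 0.073), a protein disulfide isomerase, had the largest rises. LRRC32 fell 8.96-fold (-3.16 ± 0.11). MPEG1, the pore-forming protein perforin-2, fell from 84.4 ± 5.71 to 13.0 ± 0.818 CPM, and the corepressor CBFA2T3 (-2.43 ± 0.13) and the palmitoyltransferase ZDHHC8 (-2.49 ± 0.22) fell as well. Exons of MPEG1 overlap those of DTX4. In the interferon list, 2 of 40 measured members rose, 36 fell and 2 did not pass (2 and 37 adjusted over the list alone). The median was -0.79 (camera adjusted p = 1.43e-10, and adjusted p = 0.884 with an estimated correlation). For B-cell receptor signalling, 5 of 30 measured members rose, 17 fell and 8 did not pass (5 and 17 adjusted over the list alone). The median was -0.20 (camera adjusted p = 0.00107, and adjusted p = 0.884 with an estimated correlation), and CD79A fell from 662 ± 36.1 to 295 ± 27.6 CPM. In the list of ATF4 and the unfolded protein response, 16 of 30 measured members rose, 3 fell and 11 did not pass (16 and 3 adjusted over the list alone). The median was 0.19 (camera adjusted p = 0.0204, and adjusted p = 0.884 with an estimated correlation). It lost its call without shSCR replicate 3 (adjusted p = 0.0568, the largest over 16 alternatives). Cytosolic ribosomal proteins fell, where 3 of 46 measured members rose, 21 fell and 22 did not pass (3 and 21 adjusted over the list alone). The median was -0.11 (camera adjusted p = 0.0294, and adjusted p = 0.884 with an estimated correlation), and RPS3 fell from 1565 ± 52.5 to 797 ± 22.9 CPM. That call was lost with library size alone as the scaling, with the minimum of 1 CPM, and without shSCR replicate 1 or 2 or sh72 replicate 3 (adjusted p up to 0.257). Its median ran from -0.13 to -0.061, and was -0.061 without sh72 replicate 3 and -0.07 with library size alone.

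In all, 8022 genes passed with sh72, 3879 higher and 4143 lower (4456 and 3541 with library size alone), of which 632 and 427 changed at least 2-fold, and with a minimum of 1.5-fold 1231 rose and 1176 fell. By camera 4 lists passed, and 0 with an estimated correlation (0 at an unadjusted p under 0.05, and 17 by fry).

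Genes that both shRNAs moved the same way numbered 4022, with 1970 higher and 2052 lower (2286 and 1628 with library size alone). Of these, 373 rose and 92 fell at least 2-fold with each shRNA, among them ERBB4, CD69 and LRRC32. ERBB4 had 3.57 ± 0.19 with sh68 and 3.48 ± 0.19 with sh72, and CD69 had 2.14 ± 0.24 and 2.10 ± 0.25. Calls independent between the shRNAs would give 1062.9 genes higher and 1164 lower in both. Another 1231 genes moved in opposite directions, against 2225.1 if independent. CDKN1A was one of the 1231 (0.40 ± 0.044 with sh68 and -0.33 ± 0.045 with sh72). Of these, 680 were higher with sh68 and lower with sh72 and 551 the reverse, and 38 moved at least 2-fold with each. Across genes, which are not independent replicates, the fold changes of the shRNAs had a Pearson r of 0.507 (Spearman rho 0.425). Because both are set against the same 3 control libraries, groups simulated with no effect gave an r of 0.513, so r says little here. The covariance was 0.197 against 0.0149 in those 20 simulations, which gave at most 0 genes the same way (edgeR, with at most 2 genes called for one shRNA). Part of the excess may still come from the control libraries, which are too few to be divided between the shRNAs. With a minimum of 1.5-fold, 1043 genes moved the same way (736 higher and 307 lower).

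**Figure D3:**
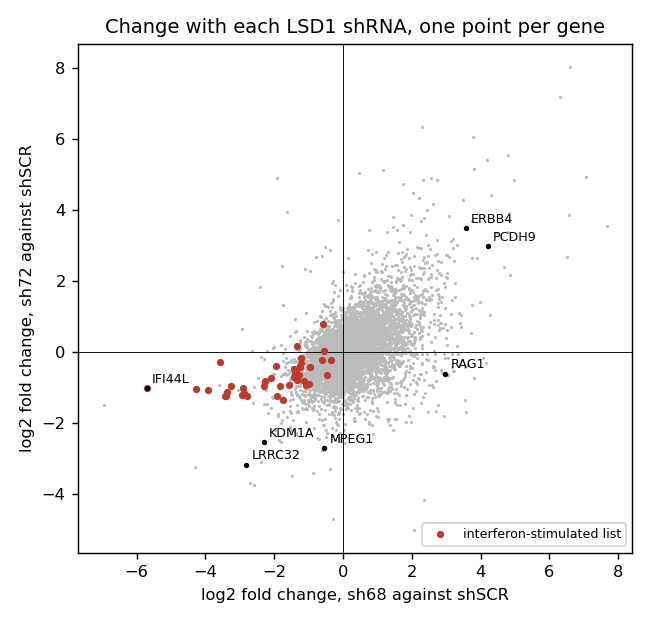
Log2 fold change against shSCR with sh72 (vertical axis) and with sh68 (horizontal axis), with 1 point per gene tested and the interferon-stimulated list in red. Most red points lie below 0 on both axes and farther from 0 with sh68, and RAG1 lies far to the right, at -0.61 on the vertical axis.

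The direct comparison of sh72 with sh68 asks where the shRNAs differ. The interferon-stimulated genes were higher with sh72: IFI44L stood at 87.1 ± 4.17 CPM against 3.36 ± 0.916 with sh68 (4.69 ± 0.093), and OASL 3.29 ± 0.16, IFIT1 3.22 ± 0.13, IFI44 2.87 ± 0.07 and DDX60 2.68 ± 0.082 followed. Genes lower with sh72 included RAG1, the recombinase of antigen receptor genes, at 2.84 ± 0.396 CPM against 33.7 ± 1.19 with sh68 and 4.29 ± 0.55 in shSCR. COL19A1 (-4.72 ± 0.24), a collagen, MYL4 (-3.74 ± 0.17), a myosin light chain, RHBDL3 (-3.71 ± 0.23) and TMEM2 (-3.62 ± 0.083), a hyaluronidase of the cell surface, were the other large ones. IL7R (-2.60 ± 0.053) was lower with sh72 too. Exons of RAG1 overlap those of RAG2, those of COL19A1 overlap LMBRD1 and those of RHBDL3 overlap C17orf75.

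In the interferon list, 37 of 40 measured members were higher with sh72, 1 lower and 2 did not pass (38 and 1 adjusted over the list alone). The median difference was 0.93 (camera adjusted p = 1.02e-16, and adjusted p = 0.659 with an estimated correlation). Of the germinal-centre list, 7 of 32 measured members were higher with sh72, 20 lower and 5 did not pass (7 and 20 adjusted over the list alone). The median was -0.44 (camera adjusted p = 0.00224, and adjusted p = 0.659 with an estimated correlation). For B-cell receptor signalling, 5 of 30 measured members were higher with sh72, 17 lower and 8 did not pass (5 and 18 adjusted over the list alone). The median was -0.16 (camera adjusted p = 0.0208, and adjusted p = 0.661 with an estimated correlation). For the neuronal targets of REST, 2 of 18 measured members were higher with sh72, 13 lower and 3 did not pass (2 and 13 adjusted over the list alone). The median was -0.84 (camera adjusted p = 0.0208, and adjusted p = 0.659 with an estimated correlation). Among cytosolic ribosomal proteins, 0 of 46 measured members were higher with sh72, 24 lower and 22 did not pass (0 and 23 adjusted over the list alone). The median was -0.11 (camera adjusted p = 0.0134, and adjusted p = 0.78 with an estimated correlation). This call was lost without sh68 replicate 2 or sh72 replicate 3 (adjusted p up to 0.115, medians over all alternatives -0.13 to -0.076). In the MYC list of the nucleolus, 26 of 30 measured members were higher with sh72, 1 lower and 3 did not pass (26 and 1 adjusted over the list alone). The median was 0.24 (camera adjusted p = 7.2e-06, and adjusted p = 0.661 with an estimated correlation). In oxidative phosphorylation, 22 of 32 measured members were higher with sh72, 4 lower and 6 did not pass (22 and 4 adjusted over the list alone). The median was 0.17 (camera adjusted p = 0.00224, and adjusted p = 0.765 with an estimated correlation). In glycolysis and hypoxia, 18 of 30 measured members were higher with sh72, 6 lower and 6 did not pass (18 and 6 adjusted over the list alone). The median was 0.33 (camera adjusted p = 0.0273, and adjusted p = 0.661 with an estimated correlation). Among heat shock genes, 8 of 12 measured members were higher with sh72, 1 lower and 3 did not pass (8 and 1 adjusted over the list alone). The median was 0.29 (camera adjusted p = 0.0208, and adjusted p = 0.661 with an estimated correlation). In the housekeeping list, 11 of 20 measured members were higher with sh72, 3 lower and 6 did not pass (11 and 3 adjusted over the list alone). The median was 0.24 (camera adjusted p = 0.0331, and adjusted p = 0.661 with an estimated correlation), a call lost with the minimum of 1 CPM and with offsets for GC content and length (adjusted p up to 0.0709, medians over all alternatives 0.17 to 0.28).

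In all, 8841 genes differed between the shRNAs, 4278 higher and 4563 lower with sh72 (4466 and 4393 with library size alone), of which 301 and 956 differed at least 2-fold, and with a minimum of 1.5-fold 867 were higher and 1954 lower. By camera 10 lists differed, and 0 with an estimated correlation (1 at an unadjusted p under 0.05, and 26 by fry).

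**Figure D4:**
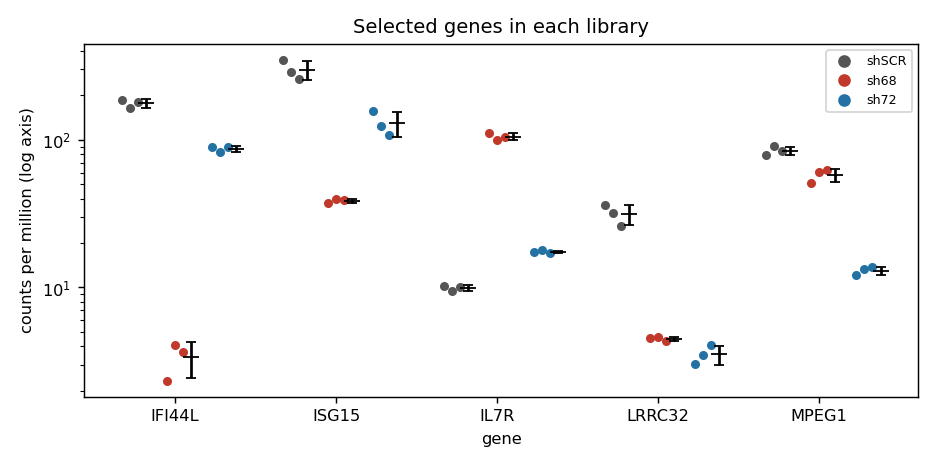
CPM on a log axis (vertical) of 5 genes (horizontal) in each library of shSCR, sh68 and sh72, with the mean and SD of each group. IFI44L and ISG15 are lowest with sh68, IL7R is highest with sh68, LRRC32 is low with both shRNAs, and MPEG1 is lowest with sh72.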

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

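The comparison of the shRNAs was planned, as were the counts of other splits of the libraries. The tests of GC content and length, scaling, a rise in the control libraries, the amount of KDM1A left, batch, T-cell RNA, natural killer cell RNA and B-cell precursor RNA were chosen after the results were seen.

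Interferon-stimulated genes were lower with both shRNAs, with a median of -1.11 on the mean. Offsets for GC content and transcript length left a median of -1.10, and the scaling that moved it closest to 0 left -1.08, which argue against these as the whole cause. A rise in the control libraries alone would put both shRNAs at the same level. Of measured members, 95% differed between sh68 and sh72, against 56.2% of all genes tested, so a difference in most members is not particular to this list. Its direction was nearly uniform, with 37 of 40 members higher with sh72. For the part shared by both, a median of -0.79 with sh72, an effect of LSD1 depletion and a rise set off by the single control shRNA cannot be told apart without another control. The lower level with sh68 is also not what the amount of KDM1A RNA left would give. Less of it was left with sh72, and the median of sh72 minus sh68 was 0.93. LSD1 protein was not measured here, so the amount of protein left stays open.

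The shRNAs against the same gene differed in 8841 genes. Were the amount of KDM1A RNA left the cause, changes shared by both would be larger with sh72. That held for 45.1% of the 1965 genes moved the same way and different between the shRNAs (886 larger with sh72 and 1079 with sh68). A difference in the LSD1 protein left, which was not measured here, stays open. With offsets for GC content and length 9209 genes differed. The labels name no batch, and each shRNA has its own 3 libraries, so a culture or library batch cannot be told apart from the shRNA. Effects of a shRNA on other transcripts, or differences between infected cell pools, stay open and were not tested, since the hairpin sequences were not used here.

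IL7R, RAG1, RAG2 and VPREB1 were higher with sh68 than in shSCR or with sh72; RAG2 and VPREB1, the surrogate light chain of B-cell precursors, were chosen after their values were seen. RAG2 stood at 6.90 ± 0.262 CPM against 0.819 ± 0.27 in shSCR and 0.734 ± 0.133 with sh72, and VPREB1 at 4.81 ± 0.232 against 0.279 ± 0.0804 and 0.248 ± 0.0526. Exons of RAG2 overlap those of RAG1, so some or all of the RAG2 rise may be reads of RAG1. A first test over 34 markers of other cell types left RNA of T cells undecided, since LCK gained 15.5 CPM with sh68, 16.3% of the 95.5 CPM that IL7R gained, on a control level of 129.8 CPM, and TCF7 went from 6.06 to 13.4 CPM (3.36 with sh72), PRF1 from 3.96 to 10.6 and KLRC1 from 1.18 to 6.10. Among CD3D, CD3E, CD3G and CD2, chosen next, the largest gain was 0.145 CPM, and of NKG7 and GNLY, abundant in natural killer cells, it was 0.0095 CPM. RNA of B-cell precursors would bring IGLL1, DNTT and CD34, whose highest mean with sh68 was 0.0394 CPM. These values lie far below the gain of IL7R or the level of RAG1. Other natural killer cell genes went both ways. PRF1, KLRC1 and KLRD1 gained 6.585, 4.92 and 0.73 CPM with sh68, and KLRB1, KLRF1 and NCAM1 at most 0.029. With sh72, KLRC1 and KLRD1 gained 5.439 and 1.007 CPM, more than with sh68. RAG1, RAG2 and VPREB1 did not gain with sh72 (-1.455, -0.085 and -0.031 CPM), and IL7R gained 7.478. The rises of KLRC1 and KLRD1 thus came without those of RAG1, RAG2 and VPREB1, which argues against RNA of natural killer cells for these genes. PRF1 goes the other way, with a gain of 1.333 CPM with sh72, so for IL7R the question is left undecided. The pattern may be a change within the sh68 cells, whose cause was not tested.

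Other splits of the libraries show how many calls a grouping can give by itself. With the 6 LSD1 shRNA libraries as 1 group, 3581 genes passed and 3 of 84 splits gave as many. The other 2 set the sh68 libraries (5057 genes, the highest) or the sh72 libraries (3985) apart, a structure of the samples. The splits thus show that libraries of a group are alike. They do not set an effect of LSD1 apart from other differences between the 3 groups. In this fit the median of the other splits was 0 genes, since breaking up a group adds to the spread. For lists in that fit, where 4 passed, 50 of 84 splits gave as many and up to 10, so chance cannot be excluded for their number. For genes moved the same way, 1 of 100 splits drawn gave as many as 4022. The next 2 took the sh68 (2971) or the sh72 libraries (2079) as the control, a structure of the samples. Any whole group taken as the control thus gave many such genes, so the count by itself does not show an effect shared by the shRNAs. The comparisons of 3 libraries with 3 have 10 splits, too few for a share under 0.05. There the real split gave 9070 genes with sh68, 7710 with sh72 and 8685 between the shRNAs, and the highest other split 0 in each by edgeR (141, 387 and 153 at an unadjusted p under 0.05). The real split gave 8 lists with sh68 (highest other 7), 4 with sh72 (highest other 7, with 5 of the 10 splits giving as many) and 9 between the shRNAs (highest other 6).

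The lists whose members differed between the shRNAs, as median log2 difference of sh72 minus sh68, were the neuronal targets of REST at -0.84, germinal-centre B cells at -0.44, B-cell receptor signalling at -0.16, cytosolic ribosomal proteins at -0.11, oxidative phosphorylation at 0.17, nucleolar MYC targets at 0.24, housekeeping at 0.24, heat shock at 0.29, glycolysis and hypoxia at 0.33 and interferon-stimulated genes at 0.93. With an estimated correlation 0 of these lists passed.

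Of the 155 genes named, 111 differed between the shRNAs by the test of the difference itself, 51 higher and 60 lower with sh72. The log2 differences of sh72 minus sh68 were, for those higher, IFI44L 4.69, OASL 3.29, IFIT1 3.22, IFI44 2.87, DDX60 2.68, RSAD2 2.29, IFIT3 2.24, USP18 2.21, XAF1 2.15, AGR2 1.92, CLEC7A 1.87, ISG15 1.75, IFITM1 1.72, CHAC1 1.35, EPCAM 0.95, SAMSN1 0.88, NOB1 0.81, GFI1B 0.79, VEGFA 0.71, ADAR 0.66, DDIT4 0.66, RNF125 0.63, CYC1 0.58, CHRNB2 0.54, EIF2AK2 0.54, PSME1 0.47, NDUFV1 0.45, CD247 0.44, CD40 0.42, PLK3 0.42, DNAJB1 0.37, PRKCB 0.33, MYBBP1A 0.32, TNRC6A 0.31, HSPB1 0.31, PGK1 0.30, NDUFB5 0.26, YWHAZ 0.25, RRP9 0.24, PSME2 0.23, LSS 0.23, CHMP2A 0.23, MVD 0.23, KIF23 0.23, TP53INP1 0.18, RCOR1 0.17, DNAJA1 0.16, SEL1L 0.16, HDAC2 0.12, BCL6 0.11 and MYC 0.10.

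For those lower with sh72, the log2 differences were COL19A1 -4.72, LYZ -4.13, MYL4 -3.74, RHBDL3 -3.71, TMEM2 -3.62, RAG1 -3.58, IL7R -2.60, ZDHHC8 -2.41, PRR5L -2.25, MPEG1 -2.16, SPARC -2.14, CCND2 -1.77, CBFA2T3 -1.67, IRF4 -1.58, CXCR4 -1.53, TNFRSF17 -1.32, PCDH9 -1.22, STAT5A -1.16, S1PR4 -1.14, GRIN1 -1.11, PART1 -1.11, CD79A -1.05, FN1 -1.01, MDM2 -0.99, PRF1 -0.99, CIITA -0.93, RPS3 -0.92, SLC2A3 -0.90, PDE4A -0.88, VLDLR -0.79, BBC3 -0.75, CDKN1A -0.74, MSMO1 -0.70, GFI1 -0.66, TMEM71 -0.64, E2F8 -0.57, NEK2 -0.55, TNFRSF10B -0.53, VPREB3 -0.50, H2AFX -0.48, COX2 -0.47, CD83 -0.41, HIST1H2BK -0.39, RPLP1 -0.39, COX1 -0.38, XBP1 -0.36, LRRC32 -0.35, CD68 -0.32, ANLN -0.30, CDC6 -0.25, DICER1 -0.25, BAD -0.24, KDM1A -0.23, PTPN6 -0.21, GPR183 -0.18, KIF2C -0.14, EZH2 -0.13, KDM1B -0.11, GINS2 -0.10 and HDAC1 -0.10. The value of LYZ rests on 4 reads with sh72 against 81 with sh68.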

How the results depend on the processing

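KDM1A, the lists that passed and the 168 passing values of named genes kept their direction under each alternative run for them, 16 for lists and 19 to 21 for genes. DESeq2, voom, the robust fit and the minimum of 1.5-fold were not run for lists. With only the groups compared, lists were counted and not followed one by one. There 4 passed on the mean, 8 with sh68, 4 with sh72 and 9 between the shRNAs. Whether more genes were called higher or lower did not hold. The larger side turned in 8 of 22 alternatives on the mean, 13 with sh68, 16 with sh72, 5 between the shRNAs and 16 for genes moved the same way. With library size alone 4475 were higher and 3689 lower on the mean, 4655 and 3947 with sh68, 4456 and 3541 with sh72, 4466 and 4393 between the shRNAs, and 2286 and 1628 the same way. RLE gave 4069 and 3910 with sh72. Library size alone moved the median of all genes by 0.033 on the mean, and the 7597 genes called under both scalings kept their sign. Offsets for GC content and length, and leaving out the MHC region and pseudoautosomal region 1, were chosen after seeing the data. Counts of genes stayed within 1.5 times of those reported under RLE, library size alone, both filters, DESeq2, voom, the block and the robust fit, except where given here. With only the groups compared, 3581 genes passed on the mean, since the difference between the shRNAs enters the spread of a 6 against 3 fit. A minimum of 1.5-fold, stricter by construction, left 2159 on the mean, 2855 with sh68, 2407 with sh72, 2821 between the shRNAs and 1043 moved the same way. A minimum of 1 CPM left 5 lists on the mean; the cause was not tested. An estimated correlation left 0 lists in each contrast, since camera then allows for the correlation within each list. With the replicate number as a block, 8631, 9173, 8436 and 9190 genes passed and 4333 moved the same way. Leaving out each library in turn gave 7152 to 8450 genes on the mean, 7873 to 9201 with sh68, 7261 to 8027 with sh72, 8092 to 8887 between the shRNAs and 3470 to 4139 moved the same way. KDM1A then ran from -2.34 to -2.27 with sh68 and from -2.59 to -2.48 with sh72, and the lists that passed numbered 5 to 8 on the mean (5 without sh68 replicate 1), 7 to 8 with sh68, 3 to 4 with sh72 and 9 to 11 between the shRNAs. Of 3575 values of named genes under alternatives, 3469 kept direction and side of the threshold, 103 lost the call and 1 gained it (CDKN1A with GC and length offsets, 0.10). CDKN1A (-0.008 without shSCR replicate 3) and KDM1B (0.004 with library size alone), which had not passed, changed sign. Of the 168 passing values, 123 passed under each alternative, 32 failed only in the 6 against 3 fit, and 13 failed under other alternatives. Among the 32 were BAD, BBC3, BCL6, CD247, CD79A, COX1, COX2, CXCR4, CYC1, DDX60, E2F8, EPCAM, FN1, GFI1, HDAC1 and HDAC2. The rest were IFI44, IFI44L, IFIT1, LYZ, NDUFB5, NDUFV1, NOB1, PLK3, RPS3, RSAD2, S1PR4, SLC2A3, SPARC, TNFRSF17, TNRC6A and VLDLR, all on the mean. No scaling moved the median of all genes by over 0.1. Depth limits genes such as CR2 and HIST2H2AC, with means of 0.14 and 0.49 CPM in shSCR.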

Other observations

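The genes of this paragraph were chosen after their values were seen, with no list or test fixed for them. The transcription factors IRF9 (-1.43 ± 0.05 with sh68 and -0.69 ± 0.048 with sh72) and STAT2 (-0.61 ± 0.057 and -0.21 ± 0.056) fell, as did IRF7 (-2.30 ± 0.27 and -0.96 ± 0.22), which amplifies interferon production. TLR7, a sensor of single-stranded RNA, fell with sh72 from 4.33 ± 0.327 to 1.11 ± 0.0581 CPM and stood at 3.79 ± 0.177 CPM with sh68, with a difference between the shRNAs of -1.77 ± 0.15 (adjusted p = 6.4e-10). LOC101060038, a placeholder name, rose from 0.616 ± 0.0258 to 20.5 ± 1.47 CPM with sh72 and stood at 0.853 ± 0.224 with sh68, a difference of 4.58 ± 0.13 (adjusted p = 5.26e-19).

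Genes next to each other on a chromosome tended to change together. This test was set before its result was seen. Pairs were taken from adjacent tested protein-coding genes without overlap, and pairs with the same symbol stem were left out. Over 10412 such pairs, the mean log2 fold changes of neighbours had a Spearman correlation of 0.115 across genes, which are not independent replicates. The highest of 1000 permutations within deciles of expression gave 0.03 (permutation p = 0.001, one-sided, the smallest they can give). The correlation was 0.144 for 6581 pairs within 50 kb and 0.063 for 3831 pairs farther apart. Shared regulation of neighbours and reads misassigned near gene ends may both contribute, and the test does not separate them. The permutations held expression but not GC content, which had a Spearman correlation of -0.073 with the mean log2 fold change. A part due to GC content was therefore not set apart either.

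Many protein-coding genes of the MHC region are absent from the table. In the region on chromosome 6, 82 of 172 were absent, 47.7%, against 17.7% of all others (odds ratio 4.25, Fisher's exact p = 2.84e-19, two-sided) and 16.4% on the rest of chromosome 6. In pseudoautosomal region 1, which has a copy on another chromosome, 14 of 16 were absent. Of genes of the region that are listed, HLA-B had 8 to 18 reads per library, TUBB 4 to 15 and CSNK2B 194 to 258, while CD74, outside the region, had 25881 to 32095. A candidate explanation, chosen after the absence was seen, is that reads matching alternate copies of the region in the genome used were not counted, which 47.7% against 17.7% fits but which the table alone cannot decide.

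Large rises were mostly in genes with few reads. On the mean of both shRNAs, 614 of the 5242 least expressed genes rose at least 2-fold and 150 fell, and of the 5242 most expressed 11 rose and 25 fell. With sh68, 917 rose and 177 fell among the least expressed, and 45 and 41 among the most expressed. With sh72 these were 517 and 286, and 6 and 42.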
